A study of Mus musculus with 6 samples.

How the data were processed

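DNase-seq was carried out on primary bone marrow-derived macrophages of C57BL/6J mice. Per the labels' protocols, nuclei were digested with DNase I at 80 U/ml for 3 min at 37 °C, fragments of 100 to 500 bp were kept, and libraries were sequenced as single-end reads of 51 bp. The 6 libraries fall into 3 groups of 2, taken from the sample titles. The LPS group received lipopolysaccharide for 8 h, the pre-treated group received Dex before the 8 h of LPS, and the late-treated group received Dex late in an 8 h LPS treatment. The labels give neither the dose of Dex nor the interval between the treatments.

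The deposited files hold a list of DNase I hotspots for each library, with no pooled list. Positions are in mm9, and reads went through CASAVA, per the submitters' processing notes. The aligner, the hotspot caller and its threshold are not given in the sources used here. Each hotspot carries a start and end, and the deposited signal values are its maximum and average tag density, per the file headers. The deposited score is a z-score, per the file headers, and the deposited p-value belongs to the same hotspot and is not stated to be adjusted. Whether positions count from 0 or from 1 is not stated, so they are printed as the files give them. The lowest listed z-score differed between libraries, from 7.98 to 11.6, so the lists do not share a z-score threshold. Because these values describe hotspots within a list, they were used to rank or filter hotspots within a list, and groups were compared by overlap of positions. The exception is an alternative that applies a common minimum z-score to all lists. Z-scores printed for several libraries describe a region in each list, and no source states that they are comparable between lists.

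Total tag numbers are unknown. In every library, 100% of the maximum densities were whole multiples of a library-specific step, within 0.1 of a step. The step lay between 0.334 and 0.443. If all lists were scaled to the same total, which no source states, the libraries would have between 0.755 and 1 times the depth of the deepest library. No counting interval was computed from these values.

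Hotspots of all 6 libraries were merged where they overlapped by at least 1 bp, and a library was said to list a region if at least 1 of its hotspots overlapped it by at least 1 bp. Exclusive regions were those listed in both libraries of a group and in neither library of the other group. Regions listed in both LPS libraries and none of the 4 Dex libraries are called LPS-only, and regions listed in all 4 Dex libraries and neither LPS library are called Dex-only. Each count was set against a no-group expectation from a Rasch-type model. That model keeps each region's number of listings and each library's number of regions, and assumes no effect of group. Its observed-to-expected ratio has a 95% interval from 1000 bootstrap resamples of 5 Mb genome blocks. The interval covers the sampling of genome regions only and not the spread between libraries. The fit was checked before use on data simulated from the same form of model, in 20 runs over 59069 regions per result. The check thus covers the fitting and not whether the model suits the lists. The mean ratio lay between 0.98 and 1.007, and single runs for the Dex-only count between 0.752 and 1.211. Planting 200 exclusive regions raised the raw count by 0.946 to 0.999 of them, which does not involve the expectation.

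Hotspot numbers and covered lengths were compared with exact two-sided permutation tests. With 2 libraries against 2 the smallest possible p is 0.333, and among the 15 ways to choose 2 of 6 libraries the smallest share is 0.0667, so none of these exact tests could pass 0.05. No parametric test between groups was run. Nothing in the labels says that the replicates came from separate animals or cultures, so p-values and SDs measure only the spread between these libraries, which may be technical. Similarity between libraries was measured as the Jaccard index, the shared length over the length covered by either list.

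The regions named in the text follow a rule fixed before the data were examined. For each comparison and direction they are the 10 exclusive regions with the highest mean within-list percentile of z-score in the libraries of their group, and the same ranking was applied to the Dex-only and LPS-only regions. Runs of neighbouring regions were named after their values were seen. Regions of a class were called a run where at least 3 followed each other with gaps of at most 100 kb, whatever regions of other classes lay between them. The number of regions in runs was compared with 10000 random draws of as many regions from those not listed in all 6 libraries.

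The alternatives were lists of equal length, holding the strongest 29347 hotspots of each library, the stronger 50% of each list, a hotspot cover of at least 50% of the region, hotspots up to 500 bp apart merged, the replicate number as a block, and each library left out in turn. A common minimum z-score of 11.6, the highest of the 6 list minimums, was added later, as was the block with lists of equal length. The 13 gene lists and 8 sequence motifs that had been fixed for tests on exclusive regions were not analysed here, nor were position classes, because no annotation or genome of mm9 was used. No gene is named for the same reason. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.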

Results

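DNase-seq maps accessible chromatin by sequencing the ends of DNA fragments that a light DNase I digestion frees from nuclei. It was applied here to macrophages grown from mouse bone marrow and treated for 8 h with lipopolysaccharide (LPS), the bacterial cell wall component that activates these cells. In 2 libraries the cells received LPS alone, in 2 they received Dex before LPS, and in 2 they received Dex late in the LPS treatment. Dex is the glucocorticoid of the study, an anti-inflammatory steroid whose receptor binds DNA. The series title places the timing of glucocorticoid treatment at the centre of the study. Untreated cells and cells given Dex without LPS were not analysed here. Regions are given by their mm9 positions alone.

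The LPS libraries listed 48084 and 51834 hotspots, the pre-treated libraries 34646 and 44686, and the late-treated libraries 29347 and 44447. The mean was 49959 ± 2652 (SD, n = 2) with LPS alone, 39666 ± 7099 (SD, n = 2) with Dex before LPS, and 36897 ± 10677 (SD, n = 2) with Dex late. The lists covered 42.4 ± 2.64, 32.9 ± 6.74 and 29.8 ± 9.03 Mb in the same order (SD, n = 2 each). Every Dex list was shorter than both LPS lists, with an exact two-sided permutation p of 0.333 for either Dex group against LPS, which is the smallest p that 2 against 2 libraries can give. The pre-treated and late-treated groups differed by less than their spread (exact permutation p = 0.667). The sign of that difference depended on single libraries. Without replicate 1 of the late-treated group the late-treated mean was higher by 4781 hotspots, and without replicate 2 of the pre-treated group it was higher by 2251. Both LPS lists also reached down to lower z-scores, 7.98 and 8.35, than the 4 Dex lists, which began between 8.98 and 11.6. From a common minimum z-score of 11.6, the mean number of hotspots fell by 4049.5 with Dex before LPS and fell by 4241.5 with Dex late, relative to LPS alone. The groups then overlapped, since replicate 1 of the LPS group had 34491 hotspots, fewer than replicate 2 of the pre-treated group (35908) and replicate 2 of the late-treated group (34802).

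**Figure D1:**
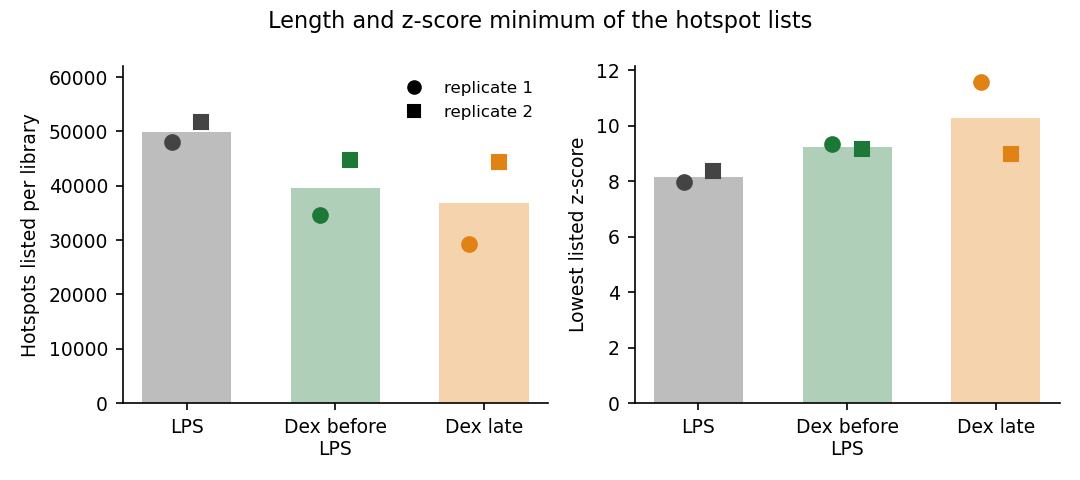
Number of hotspots listed per library (left) and the lowest z-score in each list (right) for the 3 groups, with points for the 2 replicates and bars for their mean. All 4 Dex lists are shorter than the LPS lists of 48084 and 51834 hotspots, and the shortest list, of 29347 hotspots, begins at the highest z-score, 11.6.

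Merging the 6 lists gave 59069 regions over 52.3 Mb. All 6 libraries listed 25091 of them (42.5%), with a median width of 1119 bp, and 10259 (17.4%) were listed by a single library, with a median width of 352 bp. Both LPS libraries shared 42198 regions, which were 90.9% and 83.6% of their own regions. The pre-treated libraries shared 31235 regions (95.9% and 72.9%) and the late-treated libraries 26968 (98.3% and 63.8%).

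The comparison of pre-treated cells with LPS alone asks which accessible regions change when Dex is present from before the inflammatory stimulus. Both pre-treated libraries listed 565 regions that neither LPS library listed. The strongest lay on chromosome 7 at 117259759 to 117261207, with z-scores of 61.4 and 65.2 in the pre-treated libraries. It was followed by chromosome X at 157041697 to 157043125 (49.8 and 51.7), chromosome 7 at 82614475 to 82616046 (43.4 and 50.9) and chromosome 17 at 88980516 to 88981631 (45.9 and 45.3). The 10 strongest lay on 7 chromosomes, were 1073 to 2066 bp wide and stood between the percentiles 76.7 and 88.9 of the lists.

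In the other direction, both LPS libraries listed 5007 regions that neither pre-treated library listed. The strongest lay on chromosome 1 at 54062599 to 54063607, with z-scores of 40.9 and 35.8 under LPS alone. The late-treated libraries listed this region too, at 15.1 and 12.9. Chromosome 2 at 24159744 to 24160874 followed, at 33.8 and 36.0 under LPS alone and at 13.5 and 10.6 in the late-treated libraries, and then chromosome 10 at 118465394 to 118466212, at 26.04 and 28.79 under LPS alone. Most of these regions were weak. Percentiles were averaged over every library that listed a region, including late-treated ones. The median of this mean percentile was 20.5, and 66 of the 5007 (1.32%) were above 50. The LPS lists are longer and reach lower z-scores, so regions exclusive to them come largely from their weak end by construction. Of the 565 regions, 72 (12.7%) had a mean percentile above 50 over the libraries that listed them, and these shares are not comparable between lists.

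The no-group expectation was 115 for the 565 regions, a ratio of 4.93 (95% interval 4.58 to 5.28), and 4247 for the 5007 regions, a ratio of 1.18 (1.16 to 1.20). With lists of equal length the counts were 1199 with Dex before LPS and 1424 with LPS alone, at ratios of 1.91 and 1.66, where equal lengths by construction bring the numbers of the opposite directions together. These lists are cut from the deposited ones. A region new to an exclusive set there thus lies in a deposited region that the other group listed in at least 1 library. Of the 565 and 5007 regions, 204 and 304 stayed exclusive, so most of the 1199 and 1424 were new in this way. Leaving out a library loosens the definition of an exclusive region, and with each of the 4 left out in turn the ratio for the pre-treated group lay between 1.37 and 2.22.

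The comparison of late-treated cells with LPS alone asks the same question for Dex given once the response was under way. Both late-treated libraries listed 323 regions that neither LPS library listed. The same chromosome X region at 157041697 to 157043125 was the strongest, with z-scores of 65.4 and 66.9 in the late-treated libraries. Next were the chromosome 7 region at 117259759 to 117261207 (58.2 and 52.3), chromosome 4 at 132518429 to 132520495 (52.7 and 51.5) and chromosome 12 at 26122852 to 26124365 (50.2 and 43.4). The 10 strongest were 1110 to 2066 bp wide. Of the 323 regions, 70 (21.7%) had a mean percentile above 50 over the libraries that listed them.

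Both LPS libraries listed 5446 regions that neither late-treated library listed. The strongest lay on chromosome 16 at 84584958 to 84585968, with z-scores of 30.2 and 31.5 under LPS alone and 9.89 in replicate 2 of the pre-treated group. It began right after a region at 84583150 to 84584918 that all 6 libraries listed, at z-scores of 45.1 to 69.6. Merging hotspots up to 500 bp apart joins both regions, so it was not exclusive in every alternative processing. Chromosome 6 at 143314283 to 143314924 followed, at 23.5 and 33.7 under LPS alone and at 14.97 and 20.02 in the pre-treated libraries. Here too most regions were weak. Over all libraries that listed them, including pre-treated ones, the median of the mean percentile was 20.1, and 53 of 5446 (0.973%) were above 50.

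The expectation was 33.2 for the 323 regions, a ratio of 9.73 (8.89 to 10.6), and 4849 for the 5446 regions, a ratio of 1.12 (1.11 to 1.14). With lists of equal length the counts were 1043 with Dex late and 1253 with LPS alone, at ratios of 1.88 and 1.39. There 217 of the 323 and 239 of the 5446 stayed exclusive. Most of the 1043 and 1253 thus lay in deposited regions that the other group listed in at least 1 library. With each of the 4 libraries left out in turn, the ratio for the late-treated group lay between 1.37 and 3.10.

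Set side by side, 230 regions were listed in all 4 Dex libraries and in neither LPS library. They made up 230 of the 565 regions of the pre-treated group and 230 of the 323 regions of the late-treated group. The strongest by mean percentile over the 4 libraries were chromosome 7 at 117259759 to 117261207, at a mean percentile of 87.5, and chromosome X at 157041697 to 157043125, at 87.0. Chromosome 7 at 82614475 to 82616046 (82.2), chromosome 4 at 132518429 to 132520495 (80.8) and chromosome 1 at 13444232 to 13445401 (79.4) came next. The z-scores of the 10 strongest ran from 26.4 to 66.9, while the LPS lists reached down to 7.98 and 8.35 and listed none of them. All 10 stayed Dex-only with lists of equal length, the stronger 50% of each list, a common minimum z-score, wider merging and a stricter overlap. Of the 230 regions, 31 did so. For the 10, the outcome of the cuts by length, strength and z-score was fixed beforehand. They were picked as the strongest, and the full LPS lists held none of them. The median width of the 230 was 844.5 bp and their median percentile 39.1.

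Dex-only regions stood next to each other at 5 loci, which were picked after their values were seen. On chromosome 17, between 28647329 and 28655888, 3 Dex-only regions flanked a region at 28649170 to 28651540 that all 6 libraries listed, at z-scores of 16.7 and 13.7 with LPS alone and 46.5 to 53.5 in the 4 Dex libraries. These z-scores come from separate lists and were not tested against each other. On chromosome X, 4 Dex-only regions lay between 137039944 and 137048609, the strongest at 137039944 to 137041751 with z-scores of 37.8 to 44.3. All 6 libraries listed another region in that span, at 137044361 to 137045298, with z-scores of 8.57 and 10.4 under LPS alone. Chromosome 19 held 5 Dex-only regions between 23052980 and 23132737, a span of 79.8 kb in which neither LPS library listed a hotspot. The strongest of these, at 23130783 to 23132737, had z-scores of 30.2 to 36.2. The other loci were chromosome 13 at 60927311 to 60979305, with 4 Dex-only regions, and chromosome 4 at 108879881 to 108883661, with 3. Within the chromosome 13 span, replicate 2 of the LPS group listed the region at 60940932 to 60942033, at a z-score of 9.60.

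**Figure D2:**
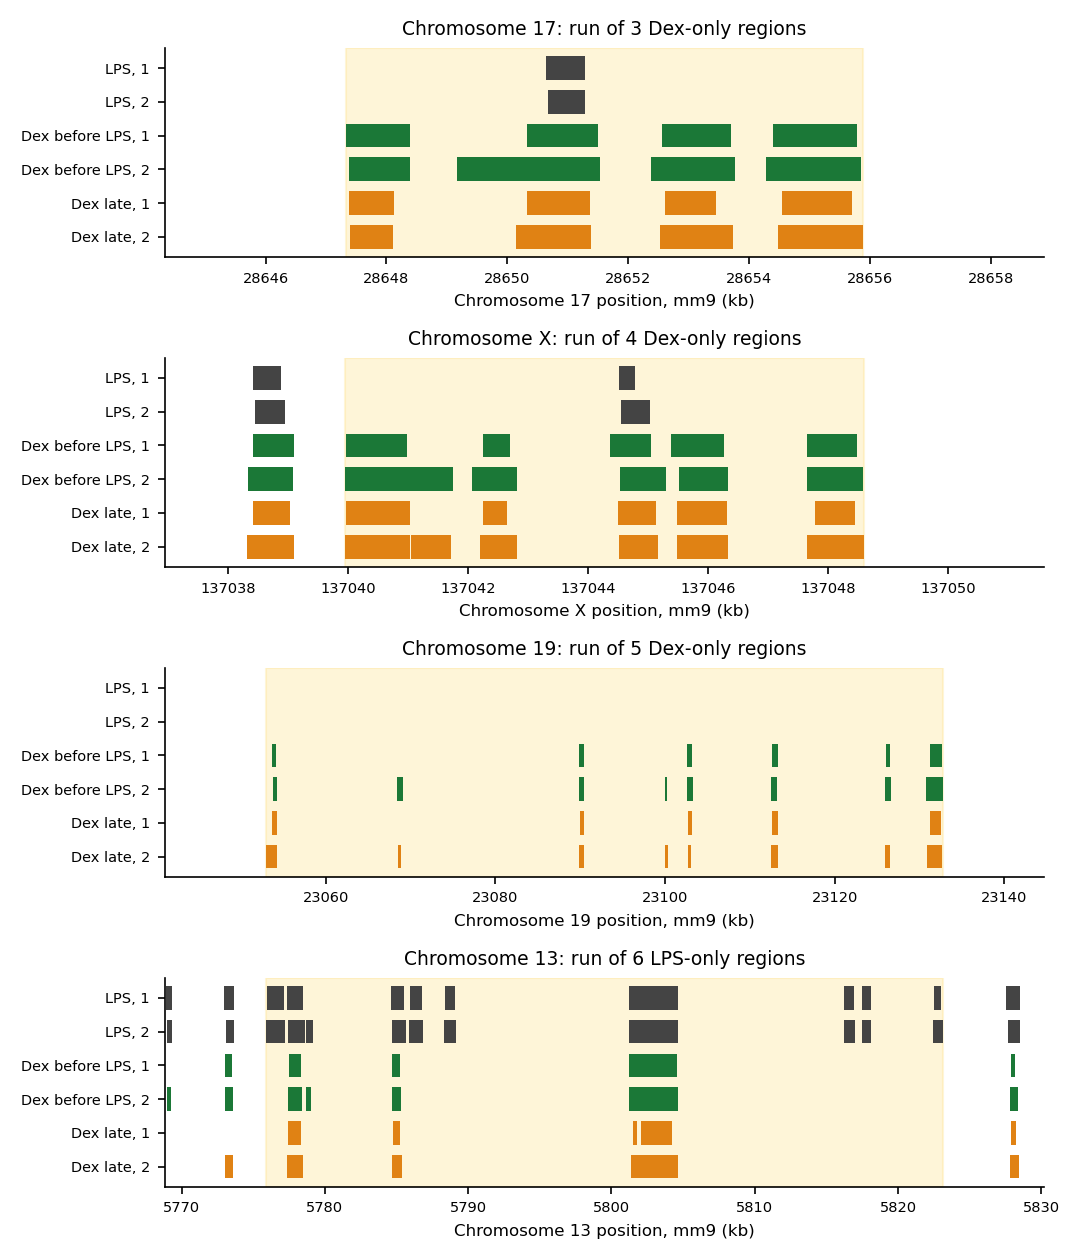
Hotspots of each library (rows, replicates 1 and 2 of each group) along 4 loci, with the mm9 position in kb on the horizontal axis, boxes for hotspots and shading for the span of a run of exclusive regions. The upper 3 panels show runs of 3, 4 and 5 Dex-only regions on chromosomes 17, X and 19, and the lowest shows a run of 6 LPS-only regions on chromosome 13.

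LPS-only regions numbered 3062. The strongest lay on chromosome 12 at 36800888 to 36801603, with z-scores of 25.7 and 24.7 and a mean percentile of 67.3. Chromosome 1 at 139849327 to 139850136 (23.2 and 22.6), chromosome 4 at 87846042 to 87847004 (19.7 and 24.7) and chromosome 15 at 30447327 to 30448194 (20.9 and 22.7) followed. These were exceptions, since the median percentile of the 3062 was 18.8, their median width was 546 bp and 46 (1.5%) were above the 50th percentile. The longest run by number held 7 LPS-only regions on chromosome 6 between 52166923 and 52272195, and another 7 lay on chromosome 9 between 66735749 and 66988867. These spans held 15 and 19 regions of any class, and several in the chromosome 9 span were listed by all 6 libraries. A run of 6 on chromosome 13, between 5775896 and 5823131, was stronger, with a median percentile of 46.1. It included a region at 5785889 to 5786864 with z-scores of 18.0 and 25.8. It surrounded a region at 5801201 to 5804649 that all 6 libraries listed at 38.9 to 50.6. All 6 libraries also listed the regions at 5777371 to 5778643 and 5784595 to 5785634. Merging across 500 bp joins the members at 5775896 and 5785889 to these, and the members at 5816212 and 5817494 to each other. So joined, the run would hold fewer LPS-only regions.

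The expectation over 6 libraries was 3.78 for the 230 Dex-only regions, a ratio of 60.9 (53.3 to 68.3), and 2199 for the LPS-only regions, a ratio of 1.39 (1.36 to 1.43). With lists of equal length there were 586 Dex-only regions, a ratio of 4.28 (3.98 to 4.60), and 671 LPS-only regions, a ratio of 2.47 (2.31 to 2.64). Of the 230 and 3062 regions, 135 and 86 kept their class there. Most of the 586 thus lay in deposited regions that an LPS library listed, and most of the 671 in deposited regions that a Dex library listed. Both Dex groups were compared with the same LPS libraries, which by itself makes their lists overlap. Simulations without a group effect redrew the listings of all 6 libraries, so the LPS lists were not held fixed. They shared 3.74 regions on average (at most 11) where 230 were observed, and 2199 (at most 2307) where 3062 LPS-only regions were observed. The simulated Dex lists behind the 3.74 were far shorter than the observed ones, 104 and 29.3 regions on average against 565 and 323. Independent lists as long as the observed ones, drawn from all 59069 regions, would share 3.09 Dex-only and 462 LPS-only regions. These values are too low for a comparison, since the real sets can only come from a smaller pool. Regions gained with Dex must be absent from both LPS lists, and regions lost must be in both. With lists of equal length the simulated overlap was 137 (at most 166) where 586 were observed, from 559 and 508 regions on average against 1199 and 1043. With each of the 6 libraries left out in turn the Dex-only ratio ran from 3.88, without replicate 2 of the LPS group, to 41.2. The LPS libraries are too few to split, and part of the excess may come from the shared controls.

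The direct comparison of the Dex groups asks whether the accessible regions differ with the timing of Dex. The length of exposure to Dex may differ between these groups too, since the labels give no interval. Both pre-treated libraries listed 903 regions that neither late-treated library listed, and 571 of these (63.2%) were also in both LPS libraries. The reverse set held 207 regions, 160 of them (77.3%) in both LPS libraries. Regions seen in a single Dex group and neither LPS library were 136 for the pre-treated group and 23 for the late-treated group. These values followed list length. At equal length, 215 of 688 regions (31.25%) of the pre-treated group and 270 of 614 (44.0%) of the late-treated group were in both LPS libraries, and 258 and 201 were in neither. None of these sets held a region as strong as the strongest Dex-only ones. The strongest of the 903 lay on chromosome 19 at 39338397 to 39338773, with z-scores of 19.2 and 20.4, and on chromosome 2 at 25707978 to 25708707, with 18.5 and 20.3, both absent from the LPS lists. The chromosome 19 region had low maximum densities, 2.88 and 2.66, where the medians of the 2 pre-treated lists were 13.6 and 12.1. The strongest of the 207 lay on chromosome 4 at 62204732 to 62205542, with z-scores of 20.4 and 18.6 in the late-treated libraries and 12.1 and 15.1 with LPS alone. Its mean percentile was 46.8. Of the 10 strongest in each direction, 0 stayed exclusive in every alternative processing. That outcome was fixed beforehand by the cut to the stronger part of each list. In replicate 1 of their own group all of them lay in the weaker part, at percentiles up to 48.7 (pre-treated) and 44.4 (late-treated). The 0 thus says nothing about the other alternatives.

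The ratios to expectation were 1.15 (1.09 to 1.21) for the 903 regions and 1.22 (1.08 to 1.37) for the 207. With lists of equal length, 688 and 614 regions were exclusive, at ratios of 1.05 (0.992 to 1.11) and 1.13 (1.06 to 1.21), so the interval for the pre-treated group included 1. With the replicate number as a block it no longer did, at 1.30 (1.23 to 1.37) for the pre-treated group and 1.42 (1.34 to 1.498) for the late-treated group, though nothing in the labels says that the numbers pair the libraries. The timing of Dex set apart 1302 regions in these lists and the replicate number 1694, with ratios of 1.44 for the number 1 libraries and 1.34 for the number 2 libraries. For either Dex group against LPS alone, by contrast, the treatment set apart more regions than the replicate number did, 2623 against 1186 with Dex before LPS and 2296 against 1337 with Dex late. The difference by timing was not larger than the difference by replicate number in these libraries.

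**Figure D3:**
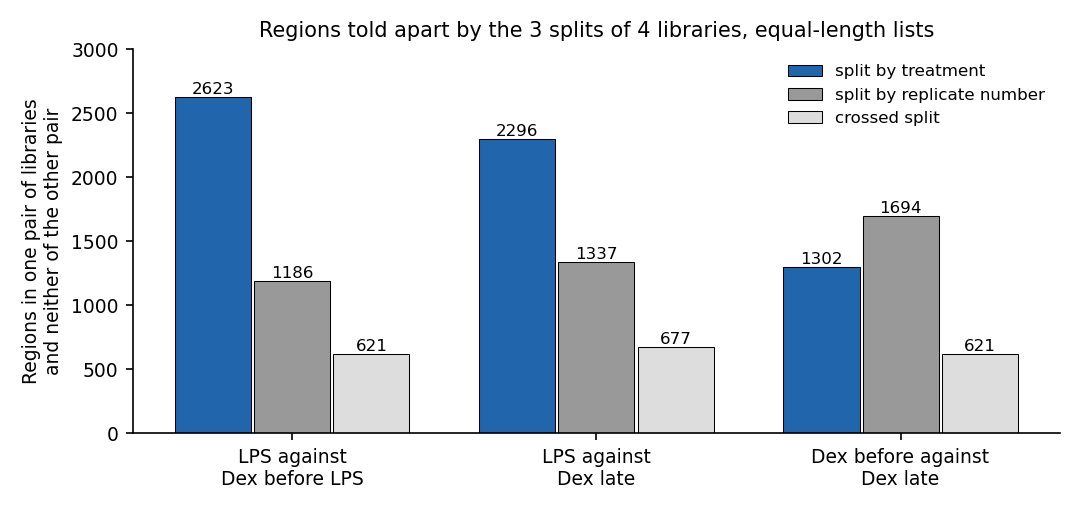
Number of regions, with lists of equal length, that are listed in both libraries of a pair and neither of the other pair, for the 3 ways to split the 4 libraries of each comparison. Treatment sets apart the most regions where LPS alone is compared with either Dex group (2623 and 2296), and replicate number does so between the Dex groups (1694 against 1302).

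Over the whole lists, the mean Jaccard index was 0.687 within groups and 0.657 between groups. The difference of 0.0304 was reached by 4 of the 15 ways to pair the 6 libraries (exact permutation p = 0.267, one-sided), where the smallest possible p is 0.0667. No chromosome stood apart, after adjustment, in its share of Dex-only or LPS-only regions among the regions not listed in all 6 libraries. The lowest Benjamini-Hochberg adjusted p of Fisher's exact test, two-sided, was 0.620 for Dex-only regions and 0.548 for LPS-only regions, and 1 chromosome in each class had an unadjusted p under 0.05. These were chromosome 2 for Dex-only regions (10 regions, odds ratio 0.509) and chromosome 13 for LPS-only regions (185 regions, odds ratio 1.20).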

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

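The common minimum z-score and the block with lists of equal length were chosen after seeing the data; the other alternatives were set before the data were examined. With 2 libraries per group, the exact permutation tests between groups could not pass 0.05 in any alternative. Every observed-to-expected ratio stayed above 1 in every alternative, while the counts followed the length and threshold of the lists. Requiring a cover of 50% or merging across 500 bp moved no count by over 1.5 times, and the Jaccard difference stayed between 0.026 and 0.0314 in all its alternatives. Tests on gene lists, motifs and position classes were not run for lack of an mm9 annotation or genome, nor was a threshold at the median strength of all lists pooled, since z-scores are not stated to be comparable between lists. Depth limits what absence means: a region missing from a list may lie just under its threshold. The total tag number is unknown, so that limit could not be set in tags. At the common minimum z-score 150 of the 230 Dex-only and 426 of the 3062 LPS-only regions kept their class, and the other members there were new. Of the regions exclusive between the Dex groups, 89 of the 903 and 67 of the 207 kept their class at equal length. In the stronger 50% of each list 0 of either set did. The highest mean percentiles in these sets were 51.1 and 46.8, so that cut drops nearly all of them beforehand.

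With lists of equal length, regions with LPS alone and not Dex before LPS numbered 1424, the reverse 1199 (ratio 1.91), with LPS alone and not Dex late 1253, the reverse 1043 (ratio 1.88), late-treated and not pre-treated 614, LPS-only 671 (ratio 2.47) and Dex-only 586 (ratio 4.28). In the stronger 50% of each list the numbers were 2512, 292 (ratio 8.25), 2670 and 133 in the same order, then 375 for pre-treated and not late-treated, 47 for the reverse, 1543 LPS-only and 114 Dex-only (ratio 139). The 375 and 47 were all other regions, with 0 of the 903 and 0 of the 207 of the deposited lists among them. From the common minimum z-score, regions with LPS alone numbered 2473 against Dex before LPS (reverse ratio 3.25) and 2454 against Dex late (reverse 629, ratio 3.36), late-treated and not pre-treated 483, LPS-only 1343 and Dex-only 348 (ratio 12.8). Hotspot numbers relative to LPS then fell by 4049.5 with Dex before LPS and fell by 4241.5 with Dex late. Cuts lower LPS-alone numbers and add only regions the other group listed, by construction. The rest was not tested.

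Leaving out a library loosens the definition of an exclusive region, so all 8 counts rose in each case. With LPS alone and not Dex before LPS they ran from 5671 to 11693 (ratios 1.04 to 1.15), the highest without replicate 2 of the pre-treated group, and the reverse from 883 to 2656 (ratios 1.37 to 2.22), the highest count and lowest ratio without its replicate 1. Against Dex late the ranges were 5767 to 15551 (1.02 to 1.13), the highest without replicate 2 of the late-treated group, and 380 to 2428 (1.37 to 3.10), the highest count without its replicate 1. Between the Dex groups they were 1111 to 5494 (1.01 to 1.16), the highest without late-treated replicate 2, and 318 to 4555 (1.04 to 1.13), the highest without late-treated replicate 1. LPS-only regions ranged from 3117 to 7730 (1.09 to 1.37), the highest without replicate 1 of the LPS group. Dex-only regions ranged from 239 to 420 (3.88 to 41.2), the highest count without late-treated replicate 1 and the lowest ratio without replicate 2 of the LPS group.

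Hotspot numbers relative to LPS stayed lower with each library left out, by -15313 to -5273 with Dex before LPS and by -20612 to -5512 with Dex late, as did covered length, by -14.3 to -4.79 and -19.0 to -6.21 Mb. Late-treated minus pre-treated ranged from -10319 to 4781 hotspots and from -9.42 to 3.35 Mb, and reversed without late-treated replicate 1 (4781 and 3.35 Mb) and without pre-treated replicate 2 (2251 and 1.73 Mb). Single libraries decided that sign.

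Groups share the replicate numbers 1 and 2, but nothing says that a number marks a shared animal or day. The differences between replicates 1 and 2 correlated across regions at 0.0588 for LPS and pre-treated, 0.0350 for LPS and late-treated and 0.251 for the Dex groups, and with lists of equal length at 0.0897, 0.101 and 0.160. With the replicate number as a block the observed counts, such as 565 and 230, stand as they are, and the ratios were 1.13 and 3.98 for LPS and pre-treated, 1.09 and 7.41 for LPS and late-treated, 1.29 and 1.44 for pre-treated and late-treated, 1.30 for LPS-only and 67.0 for Dex-only. The block with lists of equal length gave 1.73 for pre-treated and not LPS, 1.82 for late-treated and not LPS, 1.30 and 1.42 for the Dex groups (1.05 and 1.13 without the block, where the first interval included 1), 2.60 for LPS-only and 4.30 for Dex-only.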

Other observations

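The tests of list length, of other choices of libraries and of depth were chosen after the results were seen, and the test of replicate number uses a setting that was added after seeing the data. Dex-only regions tended to lie near each other. Of the 230, 19 lay in the 5 runs on chromosomes 4, 13, 17, 19 and X, where random draws gave a median of 0, a 95th percentile of 3 and at most 9 (permutation p = 0.0001, one-sided, the smallest that 10000 draws can give, Benjamini-Hochberg adjusted p = 0.0003 over 3 tests). A hypothesis is that neighbouring elements may open together at loci that respond to Dex at either timing. Regions of one locus are not independent, and which genes the loci hold was not analysed here. Some members lay close enough to be joined by merging across gaps. The gaps ran from 137041751 to 137042069 on chromosome X and from 108880517 to 108880960 on chromosome 4. Another on chromosome X began next to a region of all 6 libraries. So joined, either run would hold fewer than 3 Dex-only regions, and the test was not repeated that way. The draws were not matched for width or number of listings, for LPS-only regions either.

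The excess of LPS-only regions in runs was smaller. It was 463 of 3062 against a random median of 395 and a 95th percentile of 447 (permutation p = 0.0185, one-sided, adjusted p = 0.0277). The largest runs, on chromosome 6 at 52166923 to 52272195 and chromosome 9 at 66735749 to 66988867, held weak regions, with median percentiles of 16.40 and 18.96. The run on chromosome 13 at 5775896 to 5823131 had 46.1, but merging across gaps would join some of its members to neighbours. Dex-only regions within 100 kb of an LPS-only region numbered 92, against a random median of 87 and a 95th percentile of 99 (permutation p = 0.283, one-sided), so it stayed open whether gains and losses share loci.

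The Dex-only regions exceeded the no-group expectation 60.9 times with the deposited lists. The lists of equal length argue against list length and threshold as the whole cause of an excess. The lower bound of the ratio there was 3.98. However, the 586 Dex-only regions there were mostly other ones, in deposited regions that an LPS library listed. Of the 230, 135 were still Dex-only there and 35 in the stronger 50% of each list. Shifted hotspot boundaries are argued against by the merging across gaps, after which 90% of the 230 regions were still Dex-only, while requiring a cover of 50% kept 157 of them (68.3%). High-copy sequence stays open, as 0 of the 230 regions held a hotspot from the top 1% of density of its list, which allows up to 1.30%, above the 1% that had been set. An effect of Dex stays open too, as a hypothesis, since at equal length 1 of the 15 choices of 4 libraries, the real one, gave a ratio as large as 4.28, the next being 1.44, and 15 choices are too few for a share under 0.05.

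Whether the number of LPS-only regions comes from list length stays open, since lists of equal length, with 671 LPS-only regions in place of 3062, fixed a fall beforehand. They drop the weakest 39.0% of the shorter LPS list, where the median LPS-only region lies (percentile 18.8), and 86 of the 3062 were still LPS-only there. The excess over expectation had a lower bound of 2.31 at equal length, which argues against list length as its whole cause. At equal length 1 of the 15 choices of 2 libraries, the real one, gave a ratio as large as 2.47, the next being 1.63, but 15 choices are too few for a share under 0.05. With the deposited lists 5 of the 15 gave a ratio of at least 1.39. Apart from the real one these were pairs of Dex libraries, at 1.51 to 3.19, which a difference between Dex and LPS could give too. The highest, for replicate 1 of both Dex groups, rested on 7 regions against 2.19 expected. The remaining pairs of Dex libraries were at 0.991 and 1.07, and no pair of an LPS with a Dex library was above 1.31. A loss of accessibility with Dex stays open.

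Between the Dex groups, more regions followed the replicate number (1694) than the timing (1302) at equal length, which points to a structure that libraries of a number share. It is argued against as the whole cause of the differences by timing, because with the number as a block the lower bound of the ratio was 1.23 in the lower of the 2 directions. That bound covers the sampling of regions and not of libraries, so an effect of timing and a difference between single libraries both stay open.

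In 2 of the 3 groups the library with the shorter list had the smaller density step, which would mean more tags if all lists were scaled to the same total. Between groups the order was the opposite. All 4 Dex libraries had larger steps (0.380 to 0.443) than the LPS libraries (0.334 and 0.347), so on the same reading the shorter Dex lists had fewer tags, at 0.755 to 0.881 of the deepest library against 0.963 and 1, and depth and treatment cannot be told apart there.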
